A study of Mus musculus with 47 samples.

How the data were processed

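The series held 47 samples of mouse tissue in 6 groups: mRNA libraries of sorted nuclei from cerebellum (8) and pons (7), barcode libraries of the same nuclei (7 and 7), and PreRNA and PostRNA libraries of sorted synaptosomes (9 and 9). Per the labels' protocols, the right part of the cerebellum and both sides of the pons were dissected, nuclei were sorted by SiR-DNA and GFP, synaptosomes were sorted by a membrane dye with the V5 and HA tags, and libraries were made with the 10x 3' v3.1 chemistry. Labels tie replicate numbers to experiments: nuclei replicates 1 to 7 came from experiments 1, 25, 31, 34, 34, 35 and 36, cerebellum replicate 8 from experiment 33, and synaptosome replicates 1 to 9 from experiments 1, 25, 31, 34, 35 (4 channels) and 36.

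The deposited matrices hold raw UMI counts per feature and droplet barcode, as the authors' Cell Ranger runs wrote them, per the file headers. The submitters' processing notes name Cell Ranger 7.1.0 and build mm10. The file headers name version 6.0.1 for cerebellum replicates 2 and 8, 7.0.1 for replicates 4 and 5 of both regions, 7.1.0 for the other nuclei, version 4 for synaptosome channels 2, 3 and 4, and 7.1.0 for the other channels. How droplets were chosen is not given in the sources used here, although most nuclei matrices list a round number of droplets. Nuclei matrices hold 32285 genes, 6 construct features and both barcode features; the synaptosome matrices hold barcode UMIs per droplet, not which neuron's barcode each UMI carried, so connections between neurons were not analysed here. Gene positions came from GENCODE vM21 on mm10, where 32158 gene IDs were placed.

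Droplets with at least 300 genes and at most 5% mitochondrial UMIs were kept. Doublets were scored by simulated pairs of nuclei, and the highest scores were removed, 0.8% per 1000 nuclei and at most 20%, a rate set by rule rather than by a gap in the scores. The share removed ran from 0.546% in cerebellum replicate 2 to 20% in the largest libraries. Nuclei were clustered per region by the Leiden method of igraph 0.11.9 on a shared-neighbour graph (2000 variable genes, 30 components, 15 neighbours, resolution 1.0, seed 1). Markers of 17 classes were fixed before the data were examined, as were 31 gene lists in all, the tests and the rule for named genes. A name needed at least 3 markers found in at least 0.05 of nuclei and raised 1.5-fold over the median cluster, a lead of 0.2 on the log2 scale over the next class, and at least 100 nuclei. Clusters with median UMIs under 1.5 times the 10th percentile of their libraries' droplets were left unnamed. These naming thresholds were set after the clusters had been seen and were revised. They kept clusters with 28.0% of nuclei on average out of the classes in the cerebellum and 54.2% in the pons, and such clusters can hold damaged nuclei or free RNA.

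Counts were summed per library, because nuclei are not replicates, and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. Standard errors of log2 fold changes were computed from the F statistic. DESeq2 1.42.0 was an alternative. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated one. Named genes between the regions were, per direction, the 10 of largest fold change with an adjusted p under 0.05 and a mean of at least 50 CPM, leaving out mitochondrial genes and symbols of predicted genes, plus up to 4 members per list by lowest adjusted p. For the barcode comparisons they were the 10 of lowest adjusted p per direction plus up to 4 members per list. Clusters were described by the 5 genes of largest fold. A few genes that these rules name are not reported here.

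Shares were computed per library, with exact Clopper-Pearson intervals at a level of 0.95, and compared by two-sided exact permutation or sign-flip tests, or 100000 draws where exact enumeration was too long. Neuronal and non-neuronal nuclei were compared in libraries with at least 50 nuclei of each. As an alternative they were thinned to 500 gene UMIs, with barcode UMIs cut by the same factor as the gene UMIs of the nucleus. Barcode comparisons within a class used the library as a block and at least 20 nuclei per arm. Splits by barcode quantity used the highest and lowest 0.25 of nuclei by barcode UMIs, within 10 bins of depth and within clusters of at least 40 nuclei per library. Intervals and limits cover counting error only.

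Numbers shared between pons and cerebellum mark shared experiments in the labels, so they pair the libraries. Deviations from the group means correlated at a mean r of 0.412 for the 7 same-numbered pairs (lowest -0.00033, above 0.1 in 6) against a mean of -0.0468 for 49 other pairs. Replicates 4 and 5, both of experiment 34, were the most alike of each region, with a chi-square per degree of freedom of 17.0 in the cerebellum, where other pairs had 43.8 to 1060, and 29.1 in the pons, where other pairs had 58.7 to 332. They were counted as separate libraries, as the labels list them, but the labels do not say that they are independent, and with both summed 4464 genes differed between the regions in place of 5534. The tests were tried on simulated counts with 200 changed genes. For pons against cerebellum 80 genes were called, 4 falsely, with 8 of 67, 18 of 67 and 50 of 66 recovered at folds of 1.5, 2 and 4. For the barcode comparison of the cerebellum 86 were called, 8 falsely, with 12, 27 and 39 recovered, and for that of the pons 62 were called, 1 falsely, with 3, 21 and 37 recovered.

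Alternatives were other scaling factors, DESeq2, no filter on low counts, the replicate block, at least 600 genes, doublets kept, replicates 4 and 5 summed, other UMI thresholds, other clustering, and each library left out in turn. Alternatives without low-count clusters, with named clusters alone, without experiments 1 and 33, by version in the file headers, and the splits by barcode quantity were added after the data had been seen. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.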

Results

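Connectome-seq labels neurons with RNA barcodes that travel to their synapses, so that a barcode read from a nucleus can be matched to barcodes read from isolated synaptic terminals. The series measured nuclei from the pons and the cerebellum of mice carrying Sun1-sfGFP-Myc, a fluorescent tag of the nuclear envelope, and synaptosomes, which are pinched-off synaptic terminals. Nuclei were sorted for DNA content and green fluorescence, and synaptosomes for the V5 and HA epitope tags together. A presynaptic barcode RNA, called PreRNA or SynBarpre, was read in pons nuclei, and a postsynaptic one, called PostRNA or SynBarpost, in cerebellum nuclei. The 47 samples fell into 6 groups. They were 8 mRNA libraries of cerebellum nuclei, 7 of pons nuclei, 7 PostRNA libraries of cerebellum nuclei, 7 PreRNA libraries of pons nuclei, and 9 PreRNA and 9 PostRNA libraries of synaptosomes. The labels tie the libraries of one number to one experiment but do not say whether separate animals were used, so all p-values measure the spread between these samples, which may be technical in part.

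After filtering, the mRNA libraries held 728 to 27994 nuclei in the cerebellum and 9591 to 32000 in the pons. Gene UMIs, the unique molecular identifiers that count captured RNA molecules, came in cerebellum replicates 1 to 8 to 78773971, 3398303, 12370943, 41153985, 26202051, 87447891, 25032750 and 79086545. In pons replicates 1 to 7 they came to 133373692, 24478030, 29205300, 62931640, 44196920, 102830294 and 25975750. Median gene UMIs per nucleus lay between 752 and 8105 in the cerebellum and between 898 and 2784 in the pons. Most of the deposited matrices listed a round number of droplets, for example 35000 in cerebellum replicate 1, and large clusters close to the lowest counts of their own library were left unnamed. Unnamed nuclei made up 28.0% ± 22.7 (SD, n = 8) of cerebellum libraries and 54.2% ± 26.3 (SD, n = 7) of pons libraries.

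The largest named class in the cerebellum was granule neuron-like, the small glutamatergic neurons of the granular layer, with 47665 nuclei and 36.1% ± 16.5 of nuclei (SD, n = 8 libraries). Molecular layer interneuron-like nuclei made up 10.9% ± 11.4, ependymal or choroid plexus cell-like nuclei 8.36% ± 17.1, Purkinje neuron-like nuclei 7.06% ± 9.15, and Golgi or Purkinje layer interneuron-like nuclei 4.07% ± 5.71 (SD, n = 8). Single libraries set 3 of these means. Replicate 8 held 49.5% ependymal or choroid plexus cell-like nuclei, and the mean without it was 2.48%. Replicate 3 held 27.6% Purkinje neuron-like and 15.8% Golgi or Purkinje layer interneuron-like nuclei, and without it the means were 4.12% and 2.39%. In the pons, glutamatergic pontine neuron-like nuclei came first with 24956 nuclei and 20.3% ± 13.3 (SD, n = 7 libraries). Inhibitory neuron-like nuclei followed with 13.7% ± 13.004, oligodendrocyte-like nuclei with 7.29% ± 5.84, astrocyte-like nuclei with 2.58% ± 2.60, and monoaminergic neuron-like nuclei, the serotonin-type class, with 0.497% ± 0.489 (SD, n = 7). Several clusters came mainly from 1 library. Granule neuron-like cluster 3 took 89.3% of its nuclei from cerebellum replicate 7, cluster 5 took 96.5% from replicate 1, and cluster 6 took 97.5% from replicate 6. The antigen presentation genes H2-K1, Cd74 and B2m were among the 5 leading genes of cluster 5, and cluster 6 had the immediate early gene Egr1 among its 5 leading genes. In the pons, glutamatergic cluster 7 took 99.5% of its nuclei from replicate 1 and cluster 14 took 97.0% from replicate 6. The pituitary hormone gene Gh was among the 5 leading genes of cluster 7, and the interferon-induced gene Iigp1 among those of oligodendrocyte-like cluster 19.

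The first comparison asked which genes separate sorted nuclei of the pons from those of the cerebellum. All fold changes of this comparison are pons minus cerebellum, ± SE, over 7 pons and 8 cerebellum libraries. Hs3st4 (ENSMUSG00000078591, chromosome 7, 123982869 to 124398989, plus strand), an enzyme that sulfates heparan sulfate, was 63.1-fold higher in the pons, at 1059 ± 317 CPM against 16.8 ± 7.19 CPM (SD). Gabra6 (ENSMUSG00000020428, chromosome 11, 42306437 to 42321072, minus strand), the GABA-A receptor subunit of granule neurons, was 254-fold lower in the pons, at 1.12 ± 0.788 CPM against 290 ± 182 CPM (SD). Of 20841 genes tested, 2840 were higher in the pons and 2694 lower by edgeR's quasi-likelihood test at an adjusted p under 0.05, 5534 in all. This fit, which gave all values below unless stated, did not use the pairing of libraries by replicate number. With the replicate number as a block, which leaves out cerebellum replicate 8, 7799 of 22548 genes passed, 4476 higher and 3323 lower. Counts did not overlap between the groups for 1772 genes, where chance gives 0.0311% of genes, or 6.48. In the 5 pons and 4 cerebellum libraries whose file headers name Cell Ranger 7.1.0, edgeR called 3629 genes, 1833 higher and 1796 lower. Of the genes named by fold change, Hs3st4, Tafa1, St6galnac5, Il1rapl2, Glra1, Pcp2, Zfp385c, Clic6 and Ryr1 overlap another counted gene on the genome, so their counts are less certain where reads could be assigned to either gene. The same holds for the list members Neurod1, Gad1, Chrm2, Otx2, Slc6a4, Ddc, Folr1, Hoxb3, Rora, Uchl1, Kcnh1, Cadps2, Homer3, Tenm2, Cntn5, Cbln1, Rnf213, Usp18, Jun and mt-Nd5.

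The 10 named genes with the largest excess in the pons also held Tafa1 (log2 5.50 ± 0.42, adjusted p = 9.88e-08) and Tafa2 (4.56 ± 0.29), which encode secreted chemokine-like proteins of the brain. Ndst4 (5.17 ± 0.33), a second heparan sulfate modifying enzyme, St6galnac5 (4.33 ± 0.20), a sialyltransferase, and Kcnh5 (4.80 ± 0.25), a voltage-gated potassium channel, were among them. Neto1 (4.58 ± 0.53), an auxiliary subunit of kainate receptors, Glra1 (4.11 ± 0.40), a glycine receptor subunit of brainstem and spinal cord, Il1rapl2 (4.15 ± 0.34) and Tmem132b (4.03 ± 0.26) completed them. In the other direction stood Ttr (log2 -8.73 ± 1.97, adjusted p = 0.00327), the transthyretin gene of the choroid plexus, at 2.73 ± 7.02 CPM in the pons against 1103 ± 1635 CPM in the cerebellum (SD). Each of these means rested on 1 library. In CPM without scaling factors Ttr stood at 5850 in cerebellum replicate 8 and at 0.0808 to 1659 in the others, with a mean of 547 without replicate 8 and 1209.7 with it. It stood at 16.7 in pons replicate 2, with a mean of 0.0839 without it and 2.45 with it. The log2 value of Ttr was -7.73 without the first and -13.6 without the second. Gmnc (-6.55 ± 1.02), a gene of multiciliated cells, and Clic6 (-5.98 ± 0.64), a chloride channel gene of the choroid plexus, were also lower. Cerebellum replicate 8 set these means too. Gmnc stood at 1189 CPM there, with a cerebellum mean of 98.9 without it and 235 with it, and Clic6 at 471, with 81.7 and 130.4. Without it both calls held, at log2 -5.45 and -5.43. Neto1 stood at 5.17 without cerebellum replicate 3. The Purkinje neuron genes Pcp2 (-7.53 ± 0.57) and Car8 (-6.96 ± 0.54), the calcium pump gene Atp2a3 (-7.52 ± 0.57) and the calcium release channel gene Ryr1 (-5.73 ± 0.49) were lower too. Zfp385c (-6.30 ± 0.51) and Exph5 (-5.88 ± 0.40) completed the named genes lower in the pons.

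**Figure D1:**
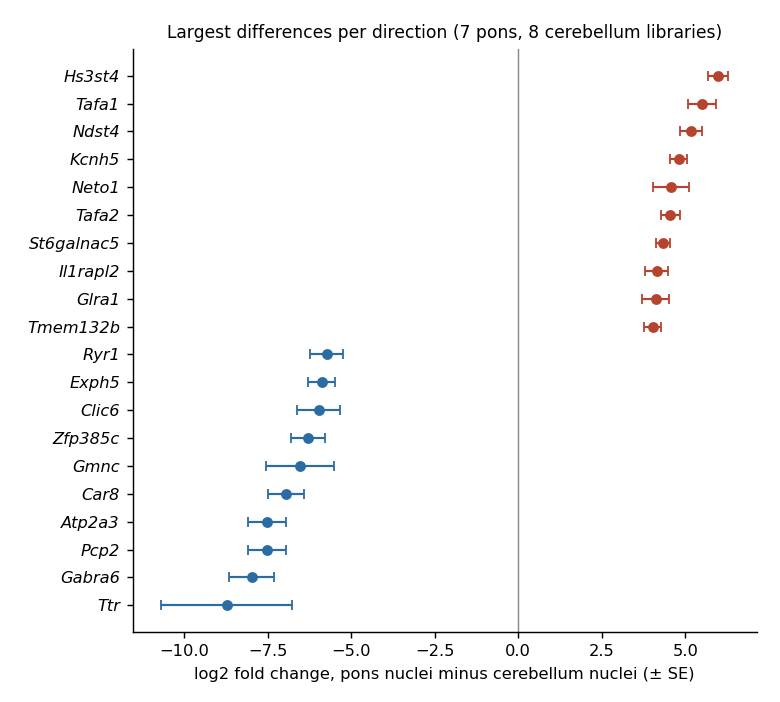
The x axis gives the log2 fold change of pons minus cerebellum nuclei and the y axis the 10 named genes of largest change per direction, with points for edgeR estimates and bars for ± SE over 7 pons and 8 cerebellum libraries. Hs3st4 at 5.98 lies highest and Ttr at -8.73 lowest, and the bar of Ttr is the widest.

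All 8 Purkinje neuron markers fell in the pons, among them Ppp1r17 (log2 -7.81 ± 0.44) and Slc1a6 (-2.71 ± 0.26), a Purkinje glutamate transporter; camera gave an adjusted p of 2.39e-21, and adjusted p = 0.0075 with an estimated correlation. All 5 measured unipolar brush cell markers fell, including the transcription factor gene Otx2 (-6.16 ± 1.02), with adjusted p = 1.41e-07 and adjusted p = 0.00221 with an estimated correlation. Otx2, which choroid plexus cells also express, was highest where Ttr was, at 235 CPM in cerebellum replicate 8, with a cerebellum mean of 20.4 without it and 47.2 with it. Without replicate 8 its call held at log2 -5.07. Of 8 granule neuron markers 6 fell and 2 did not pass, with Neurod1 (-8.12 ± 0.62) and Cbln3 (-7.89 ± 0.67) as examples; the camera call (adjusted p = 7.21e-09) was lost at adjusted p = 0.114 with an estimated correlation. Of 8 molecular layer interneuron markers 5 fell, among them Tfap2b (-5.13 ± 0.52), Pvalb (-2.71 ± 0.32) and Gad1 (-2.28 ± 0.34), 1 rose and 2 did not pass; adjusted over the list alone 6 fell (adjusted p = 0.000492; adjusted p = 0.337 with an estimated correlation). Of 7 measured Golgi or Purkinje layer interneuron markers 4 rose in the pons, including the muscarinic receptor Chrm2 (3.87 ± 0.44) and Klhl1 (1.73 ± 0.26), 1 fell and 2 did not pass (adjusted p = 0.016; adjusted p = 0.476 with an estimated correlation). Chrm2 and Klhl1 are also expressed by neurons outside the cerebellum.

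Of 6 measured monoaminergic neuron markers 4 rose in the pons, led by Tph2 (log2 3.98 ± 0.33), the rate-limiting enzyme of serotonin synthesis in the brain, the serotonin transporter Slc6a4 (5.52 ± 0.48) and Ddc (3.47 ± 0.33); 5 rose adjusted over the list alone, with adjusted p = 1.34e-06, and adjusted p = 0.0347 with an estimated correlation. Of 6 VGLUT2 neuron markers 3 rose, including the vesicular glutamate transporter Slc17a6 (3.21 ± 0.58), 1 fell and 2 did not pass (adjusted p = 0.139). The glutamatergic pontine neuron list had 1 member higher, 3 lower and 4 not passing of 8 (adjusted p = 0.112), and adjusted over the list alone 4 were lower. The inhibitory neuron list had 1 higher, 2 lower and 2 not passing of 5 (adjusted p = 0.164), with 3 lower adjusted over the list alone. Only 2 of 5 cholinergic markers were measured; 1 rose, and both rose adjusted over the list alone (adjusted p = 0.0732), with adjusted p = 0.00776 when the replicate number was a block and adjusted p = 0.326 in that fit with an estimated correlation.

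Among non-neuronal lists, 3 of 6 oligodendrocyte markers rose in the pons, among them the myelin genes Mog (log2 2.68 ± 0.56) and Mag (2.94 ± 0.69), with the same 3 counted adjusted over the list alone, while the list as a whole did not pass (adjusted p = 0.164). Of 5 endothelial markers 3 fell, including Slco1a4 (-4.46 ± 0.65) and the VEGF receptor Flt1 (-2.62 ± 0.57), and 4 fell adjusted over the list alone (adjusted p = 0.047; adjusted p = 0.449 with an estimated correlation). Of 6 ependymal or choroid plexus markers 5 fell, among them the folate receptor Folr1 (-6.22 ± 1.21), and 1 did not pass (adjusted p = 0.0431; adjusted p = 0.476 with an estimated correlation). Without experiments 1 and 33 the call of this list ended (adjusted p = 0.1096). Without cerebellum replicate 8 the cerebellum mean of Folr1 was 11.1 CPM, against 26.7 with it, and that of Slco1a4 25.1 against 39.9. Without replicate 1 that of Flt1 was 9.87 against 17.1. Their calls held, at log2 -5.05, -3.86 and -1.86. Of 8 Bergmann glia or astrocyte markers 3 fell, including Gdf10 (-5.44 ± 0.67) and the glutamate transporter Slc1a3 (-1.59 ± 0.47), and 5 did not pass (adjusted p = 0.121; adjusted p = 0.0335 with the replicate number as a block, and adjusted p = 0.558 in that fit with an estimated correlation). Of 6 oligodendrocyte precursor markers 1 rose (adjusted p = 0.578), and of 5 measured mural cell or fibroblast markers 1 fell and adjusted over the list alone 2 (adjusted p = 0.161). Of 7 microglia or macrophage markers 0 passed by edgeR, and 1 did at an unadjusted p under 0.05, the fractalkine receptor gene Cx3cr1 at log2 -1.06 (adjusted p for the list = 0.34).

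All 8 measured Hox genes, which pattern the hindbrain and spinal cord, were higher in the pons, among them Hoxb3 (log2 6.57 ± 0.55) and Hoxc4 (6.53 ± 0.50), with adjusted p = 1.85e-28 by camera and adjusted p = 0.00221 with an estimated correlation. Of 14 measured cerebellar transcription factors 11 fell, including En2 (-5.38 ± 0.58) and Rora (-2.16 ± 0.29), 1 rose and 2 did not pass (adjusted p = 1.41e-07; adjusted p = 0.0591 with an estimated correlation). Of 11 measured genes for transmitter synthesis and vesicle loading 5 rose, among them the glutamate transporter gene Slc17a8 (3.38 ± 0.45), 1 fell and 5 did not pass, and adjusted over the list alone 6 rose and 2 fell. The camera call of this list (adjusted p = 0.047) was lost with an estimated correlation (adjusted p = 0.17) and with the replicate number as a block (adjusted p = 0.0878). Of 12 measured neuropeptide genes 6 rose, including somatostatin, Sst (3.97 ± 0.67), 2 fell, including neuropeptide Y, Npy (-3.09 ± 0.53), and 4 did not pass (adjusted p = 0.0638). Sst stood at 4.59 without cerebellum replicate 1 and Npy at -3.69 without pons replicate 6.

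Lists of neuronal machinery moved in both directions. Of 18 voltage-gated potassium channel genes 9 rose, among them Kcnq5 (log2 3.31 ± 0.27), 6 fell, among them Kcnh1 (-2.40 ± 0.26), and 3 did not pass (adjusted p = 0.0076; adjusted p = 0.413 with an estimated correlation). Of 23 postsynaptic genes 11 fell, including the scaffold gene Homer3 (-5.07 ± 0.55) and the GABA-A subunit Gabrd (-4.65 ± 0.49), 3 rose, including the glycine receptor subunit Glra2 (2.87 ± 0.23), and 9 did not pass. Adjusted over the list alone 14 of these fell and 4 rose (adjusted p = 0.000954; adjusted p = 0.449 with an estimated correlation). Of 20 presynaptic release genes 5 rose, among them Stx1a (2.19 ± 0.19), a syntaxin of vesicle fusion, 3 fell, among them Cadps2 (-3.84 ± 0.46), and 12 did not pass, while adjusted over the list alone 5 rose and 7 fell (adjusted p = 0.741). Of 34 synaptic adhesion genes 10 rose, including Tenm2 (2.31 ± 0.26) and Cntn5 (3.12 ± 0.36), 9 fell, including Cbln1 (-7.20 ± 0.86; -7.98 without pons replicate 1), and 15 did not pass (adjusted p = 0.39). Of 10 measured neurofilament and axon cytoskeleton genes 3 rose, including Uchl1 (1.96 ± 0.36), 2 fell and 5 did not pass, with 4 higher adjusted over the list alone (adjusted p = 0.161).

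Of 25 interferon response genes 11 rose in the pons and 14 did not pass, with 13 higher adjusted over the list alone, among them Rnf213 (log2 1.33 ± 0.25), Usp18 (2.27 ± 0.45), Rsad2 (2.22 ± 0.50) and Ifit2 (1.92 ± 0.44), genes induced by interferon. Without cerebellum replicate 1 Usp18 and Rsad2 stood at 2.96 and 3.08. The list had adjusted p = 9.35e-05 by camera, and adjusted p = 0.476 with an estimated correlation. Without experiments 1 and 33 the preset value was adjusted p = 1.18e-13, with adjusted p = 0.0316 with an estimated correlation. Nuclei of the pons held the presynaptic barcode, and those of every cerebellum library except replicate 8 the postsynaptic one. Region and delivered construct therefore cannot be told apart for these genes, or for others of this comparison. Of 13 mitochondrially encoded genes 12 fell, including mt-Nd5 (-2.33 ± 0.38) and mt-Co1 (-2.13 ± 0.43), and 13 fell adjusted over the list alone (adjusted p = 8.61e-07; adjusted p = 0.337 with an estimated correlation). This list was set as a measure of quality in sorted nuclei, so its fall is not read as a trait of pons cells. Median mitochondrial UMIs per nucleus were 0.269% to 2.60% in cerebellum libraries and 0% to 0.472% in pons libraries. The cause was not tested. Of 16 immediate early genes 4 fell, including Jun (-1.55 ± 0.38), 2 rose and 10 did not pass (adjusted p = 0.851). Of 16 unfolded protein response genes 2 fell, Atf5 and Xbp1 (adjusted p = 0.112), and of 12 p53 targets 1 rose, Plk3 (adjusted p = 0.851); adjusted over the list alone edgeR called 0 in both. In all, 15 of 31 lists passed camera with the preset correlation, and 4 held with an estimated one, those of Purkinje neurons, unipolar brush cells, monoaminergic neurons and Hox genes. Without experiments 1 and 33, left out after the data had been seen, 10 lists passed, and the calls ended for Golgi interneuron markers (adjusted p = 0.0787), endothelial markers (0.0557), transmitter genes (0.0707) and potassium channels (0.0787). In the libraries of header version 7.1.0 alone 14 lists passed, with Golgi interneuron markers at adjusted p = 0.103, ependymal markers at 0.116, transmitter genes at 0.0755 and potassium channels at 0.105 no longer among them. Bergmann glia markers (0.000955), VGLUT2 neuron markers (0.046) and unfolded protein response genes (0.0312) were added, and these had adjusted p = 0.462, 0.389 and 0.567 with an estimated correlation.

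The share of non-neuronal nuclei asked how many sorted nuclei came from cells other than neurons. Oligodendrocyte, precursor, astrocyte, microglia, endothelial, mural and ependymal classes together made up 11.1% ± 7.83 of pons nuclei (SD, n = 7) and 11.7% ± 18.2 of cerebellum nuclei (SD, n = 8). The difference, pons minus cerebellum, was -0.549 percentage points (p = 0.976, permutation test, two-sided). Cerebellum replicate 8 held 55.7% non-neuronal nuclei, with 49.5% of its nuclei in the ependymal or choroid plexus class, and without it the cerebellum had 5.39% ± 4.02 and the difference was 5.73 percentage points (exact permutation p = 0.105). The unnamed nuclei given above stand in the denominator of these shares, and over named nuclei alone the difference was 13.1 percentage points (permutation p = 0.235).

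PreRNA was found with at least 1 UMI in 97.7% ± 4.42 of pons nuclei and PostRNA in 98.5% ± 1.61 of cerebellum nuclei (SD, n = 7 each), a difference of -0.786 percentage points (exact permutation p = 0.854, two-sided). Pons replicate 2 had the lowest share, 87.8%, and without it the difference was 0.864 percentage points. These shares are of droplets with a UMI, and free barcode RNA was not separated from barcode RNA of the nucleus. Unnamed nuclei, which are mostly close to the lowest counts, held PreRNA in 76.9% (replicate 2) to 99.9% of droplets per pons library. The barcode of the other region, which does not measure free RNA of the own barcode, was found in 0.313% ± 0.247 of pons nuclei and 0.400% ± 0.251 of cerebellum nuclei (SD). It lay below the own barcode in 7 of 7 libraries of each region that have a barcode library (exact sign-flip p = 0.0156). The labels list only PostRNA libraries for cerebellum nuclei and only PreRNA libraries for pons nuclei. This order therefore follows from the design, and its p-value does not test how specific the barcodes are. Cerebellum replicate 8, which has no barcode library, went the other way, with the presynaptic barcode in 97.9% of nuclei and 0 UMIs of the postsynaptic one. Its tissue was that of its label, since it held 1514 granule neuron-like and 364 Purkinje neuron-like nuclei, and Gabra6, Pcp2 and Car8 were higher in it than in any pons library. It held 0 UMIs of the construct transcript postsynbar6, which stood at 28.3 to 1047 CPM in the other cerebellum libraries. Which constructs it received is not given in the sources used here. With at least 10 UMIs asked, the shares were 61.4% in the pons and 70.5% in the cerebellum. With at least 50 UMIs they were 6.68% and 19.9% (exact permutation p = 0.0728), and with the replicate number as a block this difference of -13.3 percentage points passed (exact sign-flip p = 0.0312, n = 7 pairs), an alternative added after the data had been seen. Cerebellum replicate 5 held 65.4%, the next library 23.2%, and the cerebellum mean without it was 12.4%. Without pair 5 the difference was -7.82 (exact p = 0.0625). The call ended without any one of pairs 1 to 6 and held without pair 7, at -15.8 percentage points (exact p = 0.0312). Without pair 1, 2, 3, 4 or 6 the difference kept most of its size, at -14.6 to -11.9 percentage points (exact p = 0.0625 each).

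At 1 UMI the share of nuclei with barcode RNA was close to its ceiling in neuronal and in non-neuronal nuclei. In the cerebellum 98.4% ± 1.79 of neuronal and 98.7% ± 1.39 of non-neuronal nuclei held PostRNA (SD, n = 7), a difference of -0.374 percentage points (exact sign-flip p = 0.734), with mean median depths of 2552 and 3457 gene UMIs. In the pons 98.3% ± 3.15 of neuronal and 98.2% ± 2.54 of non-neuronal nuclei held PreRNA (SD, n = 7), a difference of 0.108 percentage points (exact sign-flip p = 0.812), with depths of 5207 and 2196 gene UMIs. Thinned to 500 gene UMIs, the shares were 86.1% against 81.6% in the cerebellum (exact p = 0.0469) and 74.8% against 84.7% in the pons (exact p = 0.0156). This thinning cut barcode UMIs by the gene depth of the nucleus, although they come from separate libraries, so the deeper class lost more. In both regions the deeper class had the lower thinned share. The thinned shares therefore do not show which class holds more barcode RNA. With at least 2 UMIs asked, a cerebellum call went the other way, with neurons lower. With single libraries left out its difference ran from -0.934 to -0.351 percentage points, and it passed only without replicate 7 (exact sign-flip p = 0.0312). With at least 10 UMIs asked, pons neurons exceeded non-neuronal nuclei by 14.8 percentage points (exact p = 0.0469), and the cerebellum difference was -0.547. Among nuclei within 0.5 to 2 times the library's median depth this pons call ended, at 6.23 percentage points (higher in 4 of 6 libraries, exact p = 0.219). Mean barcode UMIs per nucleus were 1.71-fold higher in pons neurons than in non-neuronal pons nuclei (log2 0.77 ± 0.43, SD, n = 7, exact p = 0.0156) and 1.03-fold higher in the cerebellum (log2 0.04). Per gene UMI the sign turned in the pons (log2 -0.47, exact p = 0.0469), and the cerebellum gave 0.27 (exact p = 0.0312). With single libraries left out the per gene UMI call held only without replicate 1 in the pons and without replicate 6 in the cerebellum. That at 10 UMIs held only without pons replicate 3, and the thinned one of the cerebellum only without replicate 3. Each ended in the other 6 of 7 runs. The 1.71-fold excess and the thinned difference of the pons passed in all 7 runs (exact p = 0.0312). Low-count clusters held 1.28-fold more barcode UMIs per nucleus than non-neuronal nuclei in the pons and 1.38-fold more in the cerebellum. The measures by UMIs and the threshold of 10 were chosen after the shares had been seen.

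**Figure D2:**
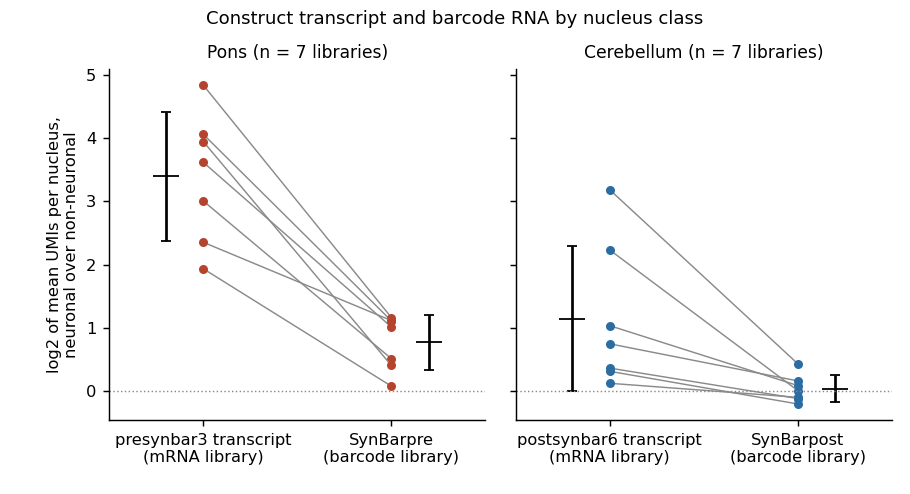
The y axis gives log2 of neuronal over non-neuronal nuclei for UMIs of the construct transcripts (presynbar3 in the pons, postsynbar6 in the cerebellum) and of the barcode RNA, with 1 point per library and mean ± SD over 7 libraries each. The transcripts lie higher, with means of 3.39 in the pons and 1.14 in the cerebellum, than the barcode RNA with 0.77 and 0.04.

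The next question was whether neurons with barcode RNA differ in expression from neurons of the same class without it. Granule neuron-like nuclei of the cerebellum and glutamatergic pontine neuron-like nuclei were compared within libraries, in 4 libraries of each region with enough nuclei lacking the barcode (cerebellum replicates 1, 4, 6 and 7, pons replicates 2, 3, 4 and 7). The arms without barcode UMIs were small, with 41 to 396 nuclei per cerebellum library and 22 to 278 per pons library. Nuclei with at least 1 PostRNA UMI differed from nuclei with 0 in 0 of 15542 genes by edgeR (924 at an unadjusted p under 0.05), and in 0 by DESeq2 (209 unadjusted). In the pons 0 of 15047 genes differed by edgeR (945 unadjusted) and 0 by DESeq2 (148 unadjusted). Without the filter on low counts edgeR called 77 genes in the cerebellum and 11 in the pons. The scaling by median ratios moved the median log2 of all genes from 0.11 to 0.00 in the cerebellum and from 0.12 to near 0 in the pons. Interferon, immediate early, unfolded protein response and p53 genes had 0 calls by edgeR in both regions, with camera adjusted p of 0.2 to 0.377 in the cerebellum and 0.749 in the pons. The mitochondrially encoded genes of the cerebellum had 0 single calls and passed camera upward (adjusted p = 0.00298; adjusted p = 0.399 with an estimated correlation). The difference of the effects, pons minus cerebellum, had 0 of 16882 genes by edgeR (914 unadjusted).

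Because nearly every nucleus had a barcode UMI, nuclei were also split by its quantity, a choice made after the comparisons above had called 0 genes. The highest 0.25 of neurons by barcode UMIs were compared with the lowest 0.25, matched for cluster and depth, and fold changes are highest minus lowest, ± SE, over 7 libraries of each region. In the pons Morrbid (ENSMUSG00000074813, chromosome 2, 128178319 to 128502765, minus strand), a long noncoding RNA, rose most clearly (log2 1.15 ± 0.07). The synaptic vesicle gene Sv2c (0.50 ± 0.06), the cadherins Cdh22 (0.58 ± 0.07) and Cdh23 (0.36 ± 0.04) and the immune checkpoint gene Vsir (0.52 ± 0.06), which overlaps Cdh23 on the genome, rose with it. Agbl1 (0.56 ± 0.07), Kcnip1 (0.48 ± 0.06), Il1rapl2 (0.41 ± 0.05) and Npas3 (0.38 ± 0.04) rose as well. The NMDA receptor subunit Grin2c (ENSMUSG00000020734, chromosome 11, 115249169 to 115267243, minus strand) fell (-0.77 ± 0.09), as did the potassium channel subunits Kcnc2 (-0.37 ± 0.05) and Kcnmb2 (-0.39 ± 0.06). Col8a1 (-0.46 ± 0.06), Pla2g4e (-0.45 ± 0.06), Pappa2 (-0.43 ± 0.06), Rmst (-0.39 ± 0.05), Ebf1 (-0.37 ± 0.06), Vat1l (-0.35 ± 0.05) and Trpc7 (-0.33 ± 0.04) fell too. Within the largest pontine cluster Pappa2 and Vat1l stood at 0.20 and 0.10.

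Fewer genes passed in the cerebellum than in the pons in this split, 33 against 623, while per gene UMI more did, 637 against 437. The semaphorin gene Sema3c (ENSMUSG00000028780, chromosome 5, 17574281 to 17730268, plus strand) rose (log2 0.33 ± 0.03), as did Xlr5a (0.33 ± 0.03), Sec61a1 (0.29 ± 0.04), a channel subunit of the endoplasmic reticulum, and the noncoding RNA Ctcflos (0.33 ± 0.05). Shb (0.51 ± 0.08), Zfhx3 (0.43 ± 0.08), Tshz2 (0.35 ± 0.06), Klhl14 (0.33 ± 0.07), the kainate receptor subunit Grik1 (0.19 ± 0.03) and the kinase Prkg1 (0.12 ± 0.02) rose as well. Malat1, an abundant nuclear noncoding RNA (-0.07 ± 0.01), and Ctnna3 (-0.07 ± 0.02) fell. Some of these genes, Sec61a1, Xlr5a, Ctcflos and Klhl14, also lead unnamed low-count clusters. Xlr5a, Sec61a1, Ctcflos, Zfhx3, Prkg1, Klhl14 and Ctnna3 overlap other counted genes, as do in the pons Morrbid, Npas3, Cdh23, Sv2c, Il1rapl2, Cdh22, Kcnip1, Pappa2, Vat1l, Pla2g4e, Ebf1, Rnf213 and Nlrc5. Calls were lost for Klhl14 and Ctnna3 without replicate 1 (adjusted p = 0.343 and 0.516), and for Malat1 and Ctnna3 without replicate 4 (0.231 and 0.842) or 5 (0.0888 and 0.301). They were also lost for Prkg1 and Malat1 without replicate 6 (0.0693 and 0.139), and for Ctnna3 without replicate 7 (0.0515).

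By edgeR 347 of 15288 genes rose and 276 fell in the pons, 623 in all, and 31 of 14940 rose and 2 fell in the cerebellum, 33 in all. Without pons replicates 1, 4 and 6 in turn the pons count was 181, 300 and 272, and without cerebellum replicates 1, 5 and 6 that of the cerebellum was 21, 21 and 19. The other splits gave in the pons 1273 genes for the unmatched highest and lowest 0.25, 437 per gene UMI, 497 with depth matched, 12 within the largest cluster, where 3 libraries could be compared, and 420 for at least 10 UMIs against fewer. In the cerebellum they gave 81, 637, 33, 0 (16 of 3405 at an unadjusted p under 0.05 by edgeR, 4 libraries) and 9 in the same order. Within the largest cluster 455 of the 569 matched pons calls tested there (80.0%) had the same direction, with a log2 fold change at a median 0.547 times that of the matched split. For the cerebellum 13 of 14 calls did, at 0.827. These nuclei are in part the same. Of the interferon genes measured in the pons, 5 of 21 rose, among them Rnf213 (log2 0.42 ± 0.07), H2-K1 (0.39 ± 0.09), Ddx58 (0.37 ± 0.09) and Nlrc5 (0.40 ± 0.11), and 7 rose adjusted over the list alone (adjusted p = 3.88e-06; adjusted p = 0.499 with an estimated correlation). The p53 target Aen rose (0.63 ± 0.17), 1 of 11 (adjusted p = 0.614). Without pons replicate 1 the calls of H2-K1, Nlrc5 and Aen were lost (adjusted p = 0.171, 0.276 and 0.367), as were that of Aen without replicate 4 (0.0656) and those of Ddx58 and Nlrc5 without replicate 7 (0.119 and 0.123). Of 13 immediate early genes 0 passed by edgeR, and adjusted over the list alone 1 fell, Homer1 (-0.15 ± 0.05; adjusted p for the list = 0.614), which passed over all genes without replicate 2 (-0.21, adjusted p = 0.000447). The unfolded protein response list (adjusted p = 0.285) and the mitochondrial list (adjusted p = 0.614) did not pass. In this split of the cerebellum none of these lists passed, with adjusted p of 0.827 for interferon, 0.381 for immediate early, 0.987 for unfolded protein response, 0.479 for p53 and 0.452 for mitochondrial genes. Other splits gave other list results, and the arms of the unmatched and per gene UMI splits differed more in depth. In the unmatched split the high arm was deeper in every library, in pons replicate 1 with a median of 10447 against 6189 gene UMIs. Per gene UMI the high arm was shallower in every library, there with 6501 against 9784. In the unmatched split the mitochondrial list passed downward, with 2 of 13 members lower in the cerebellum (adjusted p = 5.06e-07; adjusted p = 0.19 with an estimated correlation) and 10 of 13 in the pons (adjusted p = 3.87e-19; adjusted p = 0.073 with an estimated correlation). Per gene UMI it passed upward, with 11 of 13 members higher in the cerebellum (adjusted p = 1.81e-22; adjusted p = 0.0641 with an estimated correlation) and 9 of 13 in the pons (adjusted p = 6.64e-24; adjusted p = 0.0451 with an estimated correlation). It also passed upward although no single member did by edgeR, with depth matched in the cerebellum (13 members, median log2 0.03, adjusted p = 0.0101; adjusted p = 0.295 with an estimated correlation) and in the largest pons cluster (11 members, median log2 0.16, adjusted p = 0.019; adjusted p = 0.269 with an estimated correlation). The interferon list of the pons did not pass unmatched (2 of 22 members higher, adjusted p = 0.173). It passed upward per gene UMI, with depth matched and in the largest cluster, with 6 of 22, 4 of 21 and 1 of 14 members higher (adjusted p = 1.08e-11, 4.10e-06 and 4.77e-13; adjusted p = 0.0451, 0.476 and 0.233 with an estimated correlation). The unfolded protein response list of the pons passed upward per gene UMI with 1 of 11 members higher (adjusted p = 0.0131; adjusted p = 0.229 with an estimated correlation). The quantity effect differed between the regions in 178 of 16560 genes by edgeR's interaction term. That term sets pontine neurons split by PreRNA against granule neurons split by PostRNA. Region, neuron class and barcode RNA cannot be told apart in it.

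**Figure D3:**
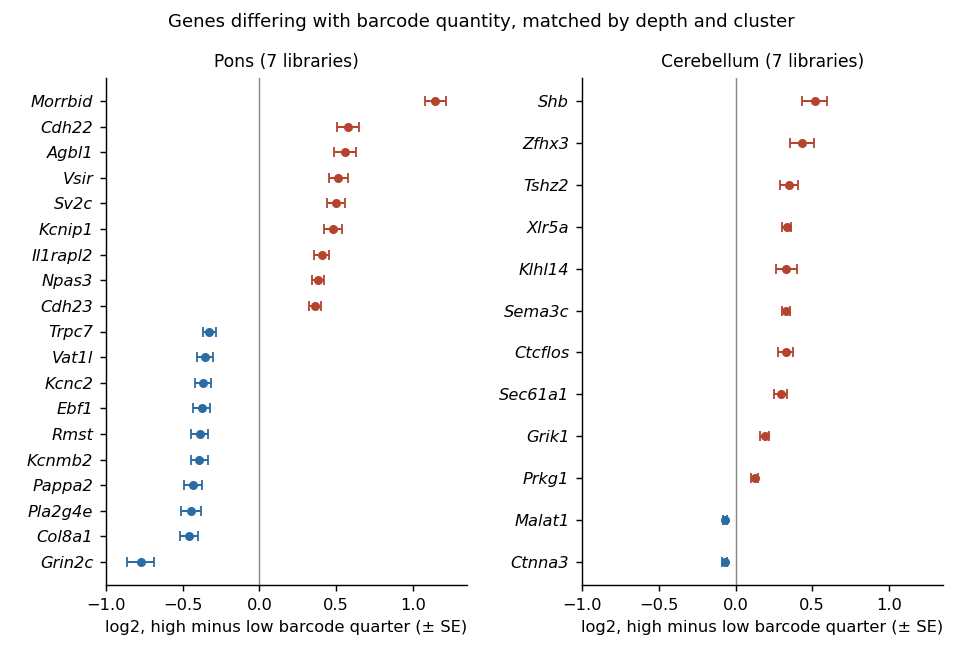
The x axis gives the log2 fold change of the highest against the lowest 0.25 of neurons by barcode UMIs, matched for cluster and depth, and the y axis 19 genes of the pons and 12 of the cerebellum, with edgeR estimates ± SE over 7 libraries per region. Morrbid at 1.15 and Grin2c at -0.77 lie outermost in the pons, and all 12 cerebellum genes lie between -0.07 and 0.51.

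Synaptosome droplets were examined for both barcode RNAs, since a synaptic terminal sorted for both tags could carry the presynaptic and the postsynaptic RNA. Droplets with PreRNA and PostRNA together were 27.6-fold more frequent in the libraries of one channel than between channels (log2 4.79 ± 1.29, SD, n = 9, higher in 9 of 9, exact sign-flip p = 0.00391, two-sided). Both libraries of one channel come from the same droplets, while different channels share droplet barcodes only by chance. This excess therefore follows from the design and does not show that a terminal carried both RNAs. The 9 channels covered 6 experiments, channels 5 to 8 all belonging to experiment 35, and 1 mean per experiment gave log2 4.65 ± 1.48 (SD, n = 6, exact p = 0.0312, the smallest possible). Channel 4 had the most, 84412 droplets with both against a mean of 1127 in mismatched channels, and channel 8 the fewest, 386 against 16.8. The droplets with both made up 9.84% to 92.3% of those with PreRNA and 0.783% to 92.8% of those with PostRNA. In the 3 channels whose headers name Cell Ranger 4 the log2 value was 4.98 (exact p = 0.25, the smallest possible), and in the 6 of version 7.1.0 it was 4.69 (exact p = 0.0312). Against the product of both droplet counts over all listed droplets the value was -0.48 (exact p = 0.191), a comparison limited by lists that hold mostly droplets with UMIs. It was below 0 in 8 of 9 channels. Channel 2, with 436376 listed droplets, stood at 1.93, and without it the value was -0.78 (n = 8, exact p = 0.00781). A list in which every droplet holds PreRNA or PostRNA forces this value to 0 or below. The list of channel 9 was of this kind, and those of channels 4, 5 and 6 nearly so. The sign and its p-value therefore say nothing about how both RNAs were placed.

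PreRNA libraries of synaptosomes held 1016 to 914492 UMIs and PostRNA libraries 23449 to 3717963. The number of droplets with PreRNA relative to PostRNA did not differ beyond the spread between channels, at log2 -0.78 ± 2.16 (SD, n = 9, above 0 in 3 of 9, exact sign-flip p = 0.359), or -0.46 over the 6 experiments (exact p = 0.312). It was -0.82 in the 3 channels of version 4 (exact p = 0.25, the smallest possible) and -0.77 in the 6 of version 7.1.0 (exact p = 0.781). Channel 8 lay lowest with 807 droplets with PreRNA and 49310 with PostRNA, and without it the ratio was log2 -0.14 (n = 8, exact p = 0.719).

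**Figure D4:**
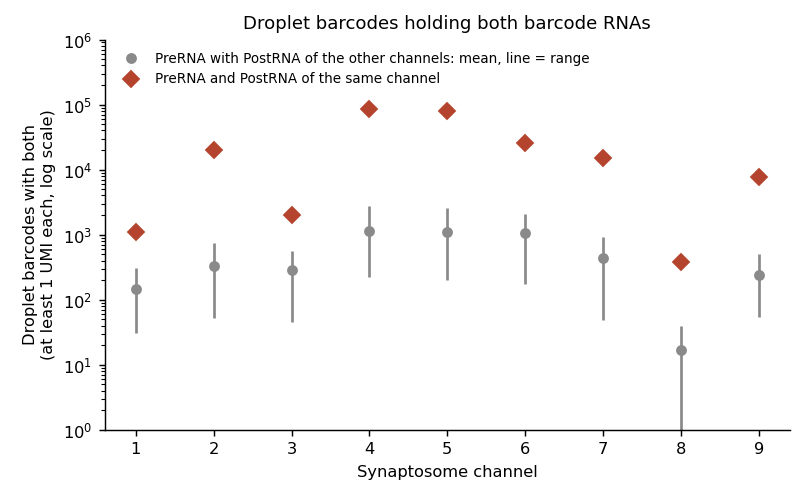
The y axis, on a log scale from 1, gives droplets with at least 1 UMI of both barcode RNAs and the x axis the 9 channels, with diamonds for matched libraries and points with bars for the mean and range over mismatched channels. The diamonds lie above the ranges in each channel, from 386 in channel 8 to 84412 in channel 4, and the range of channel 8 reaches 0, drawn at the axis floor.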

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

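Most tests in this part were chosen after the results had been seen. They were those of free RNA in the cerebellum, of depth and cluster mix, of chance by other splits, and of synaptosome droplets. They also covered barcode RNA in non-neuronal nuclei, the region difference per gene UMI and all splits by barcode quantity. The test of free RNA in the pons was written before its result.

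Genes differing with barcode quantity were weighed against free RNA. In the pons the 347 rising genes were less abundant in low-count clusters, relative to neurons, than all genes tested (log2 -0.24 ± 0.12, SD, n = 7, below 0 in 7 of 7, exact p = 0.0156). The falling genes of the same fit stood at log2 -0.043 ± 0.089 (SD). This argues against free RNA rising with barcode UMIs, as far as low-count clusters measure free RNA, since they can also hold damaged nuclei. In the cerebellum the rising genes were more abundant there (1.64 ± 0.81, n = 6, above 0 in 6 of 6, exact p = 0.0312), so free RNA may account for the cerebellum genes. Matching depth and clusters left 623 genes in the pons and 33 in the cerebellum, against 497 and 33 with depth alone. These counts argue against cluster mix, and against depth as far as it was matched, as the whole cause in either. The high arm stayed slightly deeper in every library. Its median depth was 1.0002 to 1.096 times that of the low arm in the pons and 1.008 to 1.049 times in the cerebellum. For the pons a link between gene expression and barcode quantity stays a hypothesis, and neuron subtypes finer than the clusters stay open: the largest cluster alone gave 12 genes, with fewer nuclei and 3 libraries in place of 7, and 80.0% of the calls tested there had the same direction, with log2 fold changes at a median 0.547 times those of the matched split.

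All counts of splits here include the real one. Swapping the arms within libraries gave as many pons genes in 3 of 64 splits (623 in the real split, 689 at most in another), a share of 0.0469. The first 40 splits drawn had given 0.075, and the comparison by quantity was itself chosen after others had called 0 genes. Chance is therefore not excluded for the pons genes. For the cerebellum only the real one of 64 splits gave as many (33, at most 31 otherwise). For the difference between the regions only the real one of 25 did (178, at most 111 otherwise). For nuclei with barcode RNA against nuclei without it the real count was 0, which every split reaches by construction, so these splits say nothing about chance: 32 of 32 in the cerebellum (at most 0 genes), 32 of 32 in the pons (at most 8) and 25 of 25 for the difference of the effects (at most 0). For pons against cerebellum, only the real one of 40 random splits gave as many genes (5534, at most 1210 otherwise). The same held among 40 that part all pairs (at most 1408 otherwise), so chance was excluded. The number of passing lists, 15, was reached in 3 of 40 random splits (at most 16) and 8 of 40 that part all pairs (at most 21), so chance was not excluded for that number.

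Both barcode RNAs in one synaptosome droplet, over 9 channels of 6 experiments, were weighed against independent placement and against droplets that differ in yield. If both RNAs fell into droplets independently, the number of droplets implied by their overlap would not depend on the UMI threshold, but it was higher at 1 UMI than at 3 by log2 1.45 ± 1.14 (SD, n = 9, above 0 in 9 of 9, exact p = 0.00391), which argues against it. PreRNA and PostRNA UMIs correlated over the droplets with both (Spearman 0.235 ± 0.0994, positive in 9 of 9 channels, exact p = 0.00391), which is consistent with droplets that differ in how much of both RNAs they yield. A particle that holds both RNAs, the biological reading of a double-positive sort, predicts the same correlation, so it stays open. Mismatched channels measure chance sharing of droplet barcodes and do not separate a joined particle from separate particles in one droplet.

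Barcode RNA in non-neuronal nuclei was weighed against free barcode RNA and against transduction of these cells. Low-count clusters held 1.28-fold more barcode UMIs per nucleus than non-neuronal nuclei in the pons (log2 0.35 ± 0.31, SD, n = 7) and 1.38-fold more in the cerebellum (0.46 ± 0.19, n = 6), which is consistent with free barcode RNA, although such clusters may also hold damaged nuclei. Transduction at the neuronal level predicts equal enrichment of construct transcripts and barcode RNA. The transcripts exceeded the barcode by log2 2.62 ± 0.87 in the pons (7 of 7, exact p = 0.0156) and 1.103 ± 0.98 in the cerebellum (7 of 7, exact p = 0.0156). The spread was close to the mean in the cerebellum. This counts against such transduction only if both RNAs are made and kept alike in all cells, which the sources used here do not give. Free barcode RNA would also lower the enrichment of the barcode, and transduction below the neuronal level was not addressed. Transduction of non-neuronal cells therefore stays open. Transfer of barcode RNA between cells in the tissue was not tested.

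A total of 31 groups of values were examined for a library far from the others, 7 were found, and chance gives about 5%. Cerebellum replicate 8 had a median of 8105 gene UMIs per nucleus, where the nearest library had 2877.5, and 55.7% non-neuronal nuclei, where the nearest had 14.1%. Cerebellum replicate 5 held a mean of 129 barcode UMIs per nucleus (nearest 47.4). Cerebellum replicate 1 had 805 CPM over the interferon list (nearest 268). Pons replicate 2 had the lowest share of nuclei with barcode RNA, 87.8% (nearest 98.0%). Synaptosome PostRNA replicate 4 held 3717963 UMIs (nearest 1855298). Channel 8 had a log2 ratio of droplets with PreRNA over PostRNA of -5.93 (nearest -1.94).

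The log2 difference of mean barcode UMIs between neuronal and non-neuronal nuclei was larger in the pons than in the cerebellum by 0.73 (exact permutation p = 0.00466). Per gene UMI the sign turned, with log2 -0.47 in the pons and 0.27 in the cerebellum, a difference of -0.73 (exact permutation p = 0.00117). Median depths were 5207 gene UMIs in neuronal and 2196 in non-neuronal pons nuclei, and 2552 and 3457 in the cerebellum. The effect of barcode quantity differed between the regions in 178 genes by edgeR's interaction term, in which region, neuron class and barcode RNA differ together. Cerebellum replicate 8, which has no barcode library and was used for mRNA alone, held 113094 UMIs of the presynaptic barcode in its 7692 nuclei, found in 97.9% of them, and 0 of the postsynaptic one.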

How the results depend on the processing

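The alternatives by clusters, experiments, header version and barcode quantity, and the leave-one-out runs of shares, levels and channels, were chosen after the data had been seen. Between the regions all 67 named genes kept direction and call in every setting, except Slc1a3 without experiments 1 and 33 and Mog, Mag, Usp18, Rsad2 and Ifit2 in libraries of header version 7.1.0. The gene count was 4690 to 6150 with each library left out, 7799 with the replicate block and 3629 in version 7.1.0, where fewer libraries were compared. Of the lists, 4 passed with an estimated correlation and 16 with the replicate block. Endothelial and transmitter lists lost their calls with named clusters only (adjusted p = 0.0569 and 0.124), as did endothelial, ependymal and transmitter lists without low-count clusters (0.0612, 0.0862 and 0.094). Endothelial, ependymal, transmitter and potassium channel lists lost theirs without the files of Cell Ranger 6 (0.0748, 0.116, 0.0787 and 0.137). In the last setting glutamatergic pontine and Bergmann glia markers passed (0.0104 and 0.0281; adjusted p = 0.439 and 0.576 with an estimated correlation).

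The non-neuronal share, pons minus cerebellum, reversed to 0.305 percentage points with doublets kept, 13.1 over named clusters and 5.73 with the replicate block, which leaves out cerebellum replicate 8, and was -2.83 to 5.73 with each library left out. The share with barcode RNA was -13.3 at 50 UMIs with the replicate block, which passed, -15.8 to -7.82 in that setting with each pair left out, and -1.23 to 0.864 with each left out. For neuronal minus non-neuronal nuclei, the cerebellum gave -0.758 at 2 UMIs, 4.53 thinned, 0.442 at 50 UMIs, 0.507 at 10 UMIs within 0.5 to 2 times the library's median depth, and log2 0.0398 for mean UMIs, 0.0704 without the highest 1% and 0.27 per gene UMI. The pons gave -9.89 thinned, 14.8 at 10 UMIs, 6.23 at 10 UMIs in that depth range (6 libraries, exact p = 0.219), 9.22 at 50, and log2 0.77, 0.75 and -0.47. With each library left out these shares were -0.594 to 0.152 in the cerebellum and -0.265 to 0.485 in the pons. Settings that had passed ran in the cerebellum from -0.934 to -0.351 (without replicate 2) at 2 UMIs, 3.56 to 5.51 thinned and log2 0.20 to 0.31 per gene UMI. In the pons they ran from -10.9 to -7.60 thinned, 11.9 to 17.8 at 10 UMIs, 5.82 (without replicate 6) to 10.4 at 50, log2 0.71 to 0.89 for mean UMIs, 0.68 to 0.88 without the highest 1% and -0.55 to -0.39 per gene UMI. The cause was not tested.

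Genes differing with barcode RNA were 0 in both regions without the replicate block and with each library left out, but 77 in the cerebellum and 11 in the pons without the filter on low counts. Splits by quantity gave 81, 637, 33, 33, 0 and 9 genes in the cerebellum and 1273, 437, 497, 623, 12 and 420 in the pons, for the outer 0.25 by UMIs, by UMIs per gene UMI, depth matched, depth and cluster matched, the largest cluster, and at least 10 UMIs. The difference between the regions was 388, 145 and 178 genes. With each library left out the matched splits gave 19 to 39 and 181 to 842; the cause was not tested. Among the named genes, calls were lost for 4 of 13 in the cerebellum and 4 of 26 in the pons with single libraries left out, 10 of 13 and 3 of 26 at 10 UMIs, 6 of 6 and 20 of 25 in the largest cluster, 2 of 13 and 2 of 26 unmatched, and 2 of 13 and 5 of 26 per gene UMI. Among these, Pappa2 and Vat1l reversed to 0.20 and 0.10 in the largest pons cluster, and Malat1 and Ctnna3 to 0.0218 and 0.00689 per gene UMI in the cerebellum.

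Droplets with both RNAs gave -0.48 against the product of counts (-0.78 to -0.30 with each channel left out), 4.98 in the 3 channels of version 4, too few to pass, and 4.61 to 5.04 with each channel left out. The ratio of PreRNA to PostRNA droplets kept its sign in all settings, with p = 0.386 by permutation with no replicate block and -1.05 to -0.14 with each channel left out. In simulated counts 8 of 67 genes changed 1.5-fold were recovered between the regions, and 12 and 3 of 67 in the barcode comparisons of the cerebellum and the pons; the synaptosome tests were not simulated.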

Other observations

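All tests in this part were chosen after the data had been seen. Transcripts of the delivered constructs were higher in neuronal than in non-neuronal nuclei, by amounts that varied widely between libraries. In the pons presynbar3 was 10.5-fold higher per nucleus in neuronal than in non-neuronal nuclei (log2 3.39 ± 1.02, SD, n = 7, higher in 7 of 7, exact p = 0.0156, adjusted over 6 tests 0.0234), and cre, the recombinase gene, 7.93-fold (7 of 7). Pons neurons were deeper, and per gene UMI these values were 4.45-fold and 3.36-fold (7 of 7 each). In the cerebellum postsynbar6 was 2.21-fold higher (log2 1.14 ± 1.14, SD, n = 7, higher in 7 of 7, exact p = 0.0156) and cre 4.16-fold (7 of 7), or 2.58-fold and 4.86-fold per gene UMI. The postsynbar6 excess ran from 1.09-fold to 9.08-fold. It was small in cerebellum replicates 4, 5 and 6 (log2 0.31, 0.12 and 0.36) and largest in replicates 3 and 7 (3.18 and 2.23). The transcripts prebar7 in the pons (3.31-fold, n = 5, exact p = 0.0625, the smallest possible) and postbar7 in the cerebellum (3.12-fold, n = 4, exact p = 0.125, the smallest possible) did not pass. Barcode UMIs per nucleus relative to oligodendrocyte-like nuclei were 2.13-fold in glutamatergic pontine and 1.69-fold in inhibitory neuron-like nuclei (6 of 6 libraries each), at 2.87-fold and 2.33-fold the depth. In the cerebellum they were 1.47-fold in Purkinje neuron-like (4 of 5), 1.47-fold in Golgi or Purkinje layer interneuron-like (5 of 5), 1.28-fold in Bergmann glia or astrocyte-like (5 of 5), 1.21-fold in molecular layer interneuron-like (5 of 5) and 1.09-fold in granule neuron-like nuclei (4 of 5). The depths of these classes were 2.84, 1.63, 1.18, 1.23 and 0.782 times that of oligodendrocyte-like nuclei. With 4 to 6 libraries per class the smallest exact p was 0.0312 to 0.125, so no class could pass after adjustment over all 14.

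In the pons 7 unnamed clusters were picked after their leading genes had been seen, several of them genes of pituitary hormones, with Prl and Pou1f1 leading cluster 21, Cga and Fshb cluster 23, Tshb clusters 32 and 39, and Pomc cluster 37. Clusters 20 and 30 were led by Gm14618 and Nr4a2, which are not hormone genes. Together they held 2697 nuclei and 2.25% ± 3.35 of nuclei (SD, n = 7). Pons replicates 1 and 2 held 5.42% and 8.50%, the mean without replicate 2 was 1.21%, and Gh, the growth hormone gene, reached 3723 CPM in replicate 1 and 378 CPM in replicate 2. The interferon list of experiment 1 came to 805 CPM in the cerebellum, 3.84-fold over the median of the other libraries, and to 674 CPM in the pons, 1.43-fold over it. In cerebellum replicate 2, 22 of 23 VGLUT2 neuron-like nuclei held 0 UMIs of the postsynaptic barcode, while 1 of 227 granule neuron-like nuclei did. These 23 nuclei were shallow, with a median of 485 gene UMIs against 1793 in the granule neuron-like nuclei, and 17.4% of them held the other barcode.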
